A study of Mus musculus with 40 samples.

How the data were processed

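RNA abundance was measured by 3′ tag sequencing (QuantSeq 3′ mRNA FWD, Lexogen), in which a read marks the 3′ end of a polyadenylated transcript, in macrophages grown from mouse bone marrow. Per the labels' protocols, marrow cells were cultured in medium conditioned by L929 cells, a source of the macrophage growth factor M-CSF, and then exposed to 500 ng/ml of ultrapure lipopolysaccharide (LPS) from Salmonella minnesota. The cells came from mice with a loxP-flanked Otulin gene, either without Cre (WT here) or with Cre recombinase expressed from the Lyz2 locus (LysM-Cre; KO here). Otulin encodes a deubiquitinase that removes linear ubiquitin chains. Libraries were made before LPS (0 h) and after 3, 6, 12 and 24 h, with 4 biological replicates per genotype and time, which gave 40 libraries in 10 groups.

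The authors deposited 1 table of expected counts per Ensembl gene, not normalized. Per the submitters' processing notes, which give neither the order nor the role of the tools, FastQC 0.11.9, cutadapt 3.7, STAR 2.7.10a, UMI-tools 1.1.2, RSEM 1.3.3 and the mouse genome build GRCm39 were used. The settings, the annotation release, the handling of strand and whether molecular identifiers were collapsed are not given in the sources used here. A tag at the 3′ end counts a transcript once whatever its length. Genes that overlap at their 3′ ends or have close copies, such as pseudogenes, can share tags, so their values are less certain. The expected counts were all whole numbers as deposited, so rounding them for the count models had no effect. The table held 57010 gene identifiers, of which 52029 were paired with a symbol through GENCODE vM21 (GRCm38). Because that assembly is not the build of the table, no coordinates are printed, and the RefSeq gene table (GRCm38.p6) served only to find neighbouring genes.

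Library totals ran from 3615155 to 6829303 counts, with a median of 4471933 over the 40 libraries, 4535400 in KO and 4450200 in WT. At this depth a gene with a mean of 5 CPM (counts scaled to library size) rests on roughly 20 counts per library, and lower genes are measured less precisely. All 60 pairs of replicates within a group differed by more than sampling noise: over genes with at least 20 counts per pair, chi-square per degree of freedom ran from 2.34 to 18.9. Each library was therefore counted as 1 replicate.

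Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (minimum count 10), a robust quasi-likelihood fit, the quasi-likelihood F-test and Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. KO and WT were compared at each time in a fit of that time's 8 libraries. The response to LPS was tested within each genotype in a fit of its 20 libraries, each time against 0 h. Whether the response differed between genotypes was tested as an interaction over the 16 libraries of 0 h and one later time. Log2 fold changes are edgeR's with a prior count of 0.125, their standard errors (SE) are the absolute log2 fold change over the square root of F, and CPM use TMM-scaled totals. All p-values are two-sided.

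Gene lists were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists with at least 5 measured members. There were 36 lists, covering cytokine, interferon, metabolic, stress and cell type genes. Those for dendritic cells, red cell and platelet precursors, lymphoid cells, mast cells and basophils, and stromal cells had too few measured members at every time and were not tested between genotypes, and the neutrophil list was not tested at 0 h. Camera with an estimated correlation and fry were run beside it. Camera compares a list with all other genes, whereas fry asks whether the list's own genes moved one way on balance.

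The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names 8 genes in every comparison: Otulin, Lyz2, Tnf, Il1b, Il6, Nlrp3, Ripk3 and Mlkl. For KO against WT it adds the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 5 CPM and no overlap between the 4 KO and 4 WT values. It also takes up to 4 called members of each called list, or of a list with at least 3 called members, or, where a called list had none, its 2 members with the smallest p, as values. For LPS it takes the 5 highest and 5 lowest changes in WT at 3 h and 24 h, and it would have added genes called one way at all 5 times, of which there were 0 among the 9788 genes tested at each time. Genes whose symbol is Gm with a number or ends in Rik, those without a symbol and pseudogenes were counted but not named. Genes named outside the rule are said to be so. A gene that the rule names at 3 h is not reported here.

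The labels number the replicates 1 to 4 in each group. Within a genotype the same number was taken to mark the same animal across times, which the labels do not state. Deviations from the group means correlated between libraries of the same genotype and number at different times (mean r across genes 0.144, over 0.1 in 47 of 80 pairs). Between different numbers the mean r was −0.0472 (over 0.1 in 10 of 240 pairs). Deviations sum to 0 within a group, so that second mean is tied to the first and is no separate control. By animal the first ran from 0.0818 in WT 3 to 0.287 in WT 4, with KO 3 (0.218) next highest. Xist and Y-linked transcripts sorted the 8 animals so defined the same way at every time: KO 3 and WT 4 were male and the other 6 female. A number shared by a KO and a WT animal did not pair them. The male animals and counts summed over the 5 libraries of each animal were examined as alternatives chosen after seeing the data.

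The procedures were tested on simulated counts drawn from the means and depths of these libraries, with 100 genes changed 1.5-fold and 100 changed 2-fold. For KO against WT at 6 h (10362 genes) edgeR recovered 53 and 85 of them, with 6 false calls. For LPS in WT at 24 h (11755 genes) it recovered 48 and 80, with 6 false calls, and for the interaction at 6 h (11845 genes) 26 and 69, with 4 false calls. A shift of 0.3 log2 in 41 interferon response genes at 6 h was called by camera, by camera with an estimated correlation and by fry. Of 30 other lists 0 were called by any of these. The simulated genes varied independently of one another, so this does not measure false list calls among correlated genes. Apart from the changed genes, the simulated groups shared one mean per gene, without the wide response to LPS. In the data 8489 of 12151 genes were called for LPS in WT at 24 h. The simulated LPS and interaction figures therefore need not hold for the tests on the data. Alternatives were DESeq2 1.42.0 and its size factors, no filter, other sets of libraries, the replicate number as a block, limma with the animal as a random effect (statmod 1.5.0), and leaving out each library.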

Results

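The data are gene counts from 40 libraries of mouse bone marrow-derived macrophages, primary macrophages grown from marrow, with a floxed Otulin gene and either no Cre (WT) or LysM-Cre (KO). No group carried Cre without the floxed gene. In every difference between KO and WT below, loss of Otulin and presence of Cre therefore cannot be told apart. Cells were sampled before LPS and after 3, 6, 12 and 24 h of LPS, a bacterial cell wall component that activates macrophages through the receptor TLR4, with 4 biological replicates per genotype and time. Library totals ran from 3615155 to 6829303 counts. After the filter on low counts over all libraries 12522 genes were kept, 98.4% of them with a symbol. On the first principal components, which held 47.0% and 25.3% of the variance, the libraries grouped by time, with both genotypes of a time side by side. At 6 h the genotypes did not overlap on the first component, with KO at 48.0 to 49.6 and WT at 39.3 to 46.8. Libraries of KO 3 and WT 4 came from male animals by Xist and Y-linked counts, and the other 6 animals were female. Xist lay at 227 to 606 CPM in the female libraries and at 0.251 to 2.24 CPM in the male ones.

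**Figure D1:**
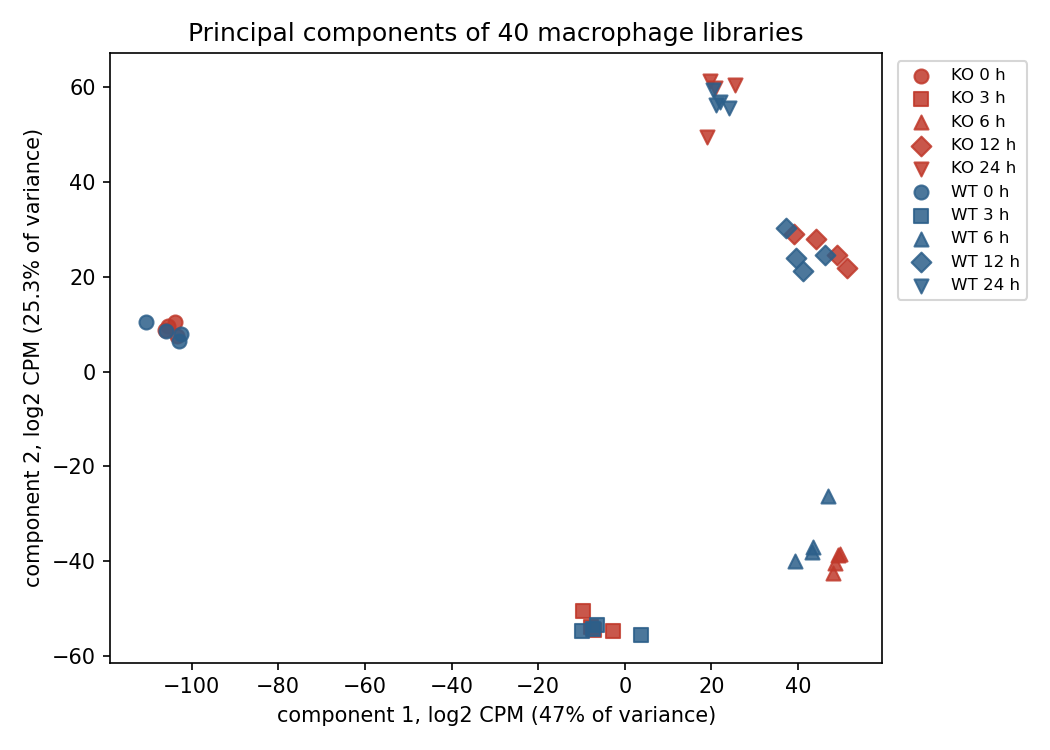
Principal components 1 (47.0% of variance) and 2 (25.3%) of the log2 CPM of the 40 libraries, 1 point per library, coloured by genotype and shaped by hours of LPS. Libraries group by time, and KO and WT libraries of one time lie close together.

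Otulin, the targeted gene (ENSMUSG00000046034), was counted in every library of both genotypes. It lay at 35.9 ± 6.05 CPM in KO and 41.1 ± 2.85 CPM in WT at 0 h (mean ± SD, n = 4), and at 32.5 ± 1.06 and 43.1 ± 4.74 CPM at 3 h. At 6 h it lay at 31.1 ± 2.17 and 37.5 ± 3.17 CPM, at 12 h at 32.9 ± 3.87 and 32.9 ± 1.95 CPM, and at 24 h at 48.5 ± 3.20 and 32.2 ± 4.83 CPM. Single libraries ran from 27.6 CPM in KO 3 at 12 h to 51.7 CPM in KO 4 at 24 h among KO, and from 27.6 to 47.5 CPM among WT. The KO minus WT difference was −0.21 ± 0.11, −0.41 ± 0.098, −0.29 ± 0.11, −0.01 ± 0.12 and 0.59 ± 0.11 log2 (SE) at 0, 3, 6, 12 and 24 h. None of the 5 passed the test (edgeR adjusted p = 0.685, 0.0564, 0.291, 0.989 and 0.0704). The labels do not state which exons the Cre removes. A tag from the 3′ end outside the deleted part is counted with or without the deletion, so these values do not check the genotype labels.

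Lyz2 (ENSMUSG00000069516), which encodes lysozyme and whose locus carries the Cre insertion in LysM-Cre mice, was lower in KO at 3, 6 and 24 h. The differences were −0.47 ± 0.094 log2 (SE; edgeR adjusted p = 0.0258), −0.44 ± 0.075 (adjusted p = 0.00752) and −0.59 ± 0.0998 (adjusted p = 0.0387). At 6 h it lay at 2320 ± 208 CPM in KO and 3112 ± 205 CPM in WT (SD, n = 4). At 0 h and 12 h the differences were −0.40 ± 0.11 (adjusted p = 0.360) and −0.49 ± 0.14 (adjusted p = 0.310). Leaving out 1 library did not end the call at 6 h. It was lost at 3 h without KO 3, KO 4, WT 1, WT 3 or WT 4 (highest adjusted p = 0.0972) and at 24 h without KO 1, KO 2, KO 3, WT 2 or WT 4 (highest adjusted p = 0.142). It was also lost at 3 and 6 h in 1 fit of all 40 libraries and by limma with the animal as a random effect, and at 24 h with sex as a covariate. Without the 2 male animals, a choice made after seeing the data, the calls at 3 and 24 h were lost.

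LPS changed most measured genes in WT cells within hours. Il1b, an inflammatory cytokine, rose by 8.82 ± 0.40 log2 at 3 h (SE, n = 4) and was still 6.12 ± 0.39 above 0 h at 24 h. Tnf rose by 4.79 ± 0.23 at 3 h and was 1.79 ± 0.22 above 0 h at 24 h. Il6, another cytokine, rose by 10.09 ± 0.77 at 3 h from 6 counts over the 4 libraries at 0 h. Nlrp3, an inflammasome sensor, rose by 2.50 ± 0.20 at 3 h and differed by −0.06 ± 0.22 at 24 h (adjusted p = 0.830). Mlkl, the executor of necroptosis, rose at each time, by 1.68 ± 0.12 at 3 h and 2.96 ± 0.11 at 24 h. The largest rises at 3 h beside Il6 were those of the protease gene Adamts4 (9.85 ± 0.20) and the endothelin gene Edn1 (9.60 ± 0.52). These started from 4 and 5 counts over the 4 libraries at 0 h, so their size is uncertain. Itgb8 and Shisa3, also among the 5 highest, had 0 counts at 0 h and lay at 25.9 ± 2.52 and 23.5 ± 4.40 CPM (SD) at 3 h. The largest falls at 3 h were Cnr2 (−3.97 ± 0.16), Rhov (−3.71 ± 0.38), Sox4 (−3.67 ± 0.23), Lyl1 (−3.56 ± 0.22) and Usp2 (−3.48 ± 0.17).

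At 24 h the top of the WT response held the interferon-inducible genes Slfn4 (9.53 ± 0.39), Oasl1 (9.30 ± 0.19) and Cxcl9 (8.50 ± 0.34) and the complement factor gene Cfb (8.83 ± 0.20). Slfn1, also among the 5 highest, had 1 count at 0 h and lay at 79.2 ± 8.29 CPM at 24 h. Cxcl9 had 6 counts over the 4 libraries at 0 h. The bottom held Nanos1 (−6.50 ± 0.41), Pald1 (−6.39 ± 0.40) and the mitosis genes Aspm (−5.28 ± 0.18), Cdc20 (−5.28 ± 0.26) and Ccnb2 (−5.24 ± 0.25). Nanos1 and Pald1 had 4 and 6 counts over the 4 libraries at 24 h, so the size of their falls is uncertain. Apart from Nlrp3 at 24 h, each change given here passed edgeR's test, the weakest being Tnf at 24 h (adjusted p = 1.35e-06). By list, all 42 measured members of the type 1 interferon response rose at 6 h, as did all 18 interferon gamma-inducible GTPases and targets and all 17 chemokines. Their medians were 5.35, 6.21 and 5.01, and the first was 5.18 with the 1 member of 0 to 3 counts at 0 h set at a floor of 3 counts over the group. Of 23 genes of the NF-κB pathway and its feedback 21 rose at 6 h and 0 fell, and the same counts held at 24 h. Of 34 cell cycle genes 31 fell at 6 h and 32 at 24 h (medians −1.54 and −2.58), and 1 rose at each. Of 22 cholesterol synthesis genes 10 fell and 4 rose at 6 h, and 19 fell and 0 rose at 24 h. All 16 class I antigen presentation genes were higher at both times. In the linear ubiquitin machinery, the group of genes to which Otulin belongs, 12 of 16 rose and 4 fell at 24 h. Of 7 neutrophil markers 6 rose and 0 fell at 6 h, and 4 rose and 1 fell at 24 h. Of 10 monocyte markers 6 rose at both, with 0 falling at 6 h and 3 at 24 h. Of 7 osteoclast markers 1 rose and 3 fell at 6 h, and 1 rose and 5 fell at 24 h.

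In all, 6640 of 12151 genes changed at 3 h in WT (3235 higher, 3405 lower) and 8277 at 6 h (3772 and 4505). The counts were 8282 at 12 h (3924 and 4358) and 8489 at 24 h (4193 and 4296). In KO, 5853 of 12037 genes changed at 3 h (2756 and 3097) and 7791 at 6 h (3460 and 4331). The counts were 7797 at 12 h (3699 and 4098) and 7917 at 24 h (3944 and 3973). Il1b rose in KO by 9.24 ± 0.37 and Tnf by 4.98 ± 0.11 at 3 h. All 42 interferon response genes rose at 6 h (median 5.29, or 5.19 with 1 member at that floor), and 30 of 34 cell cycle genes fell at 6 h (median −1.73). Across 11875 genes tested in both genotypes, 5248, 7108, 7109 and 7217 were called in both at 3, 6, 12 and 24 h. Independent lists would share 3186, 5283, 5300 and 5504. Of these 5248, 7108, 7109 and 7216 moved the same way. Pearson's r of the fold changes across genes, which are not independent replicates, was 0.966, 0.970, 0.972 and 0.965.

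Otulin itself rose in KO by 0.44 ± 0.11 log2 at 24 h (adjusted p = 0.00104, n = 4) and fell in WT by 0.36 ± 0.10 (adjusted p = 0.00334). The difference of these responses was 0.80 ± 0.17 (edgeR adjusted p = 0.372) and did not pass the test.

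Before LPS, 0 of 11734 genes passed edgeR's test between KO and WT, while 900 had an unadjusted p under 0.05 and DESeq2 called 27. The matrix metalloprotease genes Mmp12 and Mmp9 differed by 0.65 ± 0.10 and 1.45 ± 0.32 log2 (SE, n = 4; adjusted p = 0.124 and 0.253). Atp6v0d2, a proton pump subunit of lysosomes and osteoclasts, differed by 0.59 ± 0.14 (adjusted p = 0.286). As groups, TGF-β and matrix genes (15 of 17 above 0, median 0.12) and oxidative phosphorylation genes (34 of 38, median 0.12) were higher in KO than other genes by camera, but not with the correlation estimated from the data (adjusted p = 0.704 and 0.747 with an estimated correlation). The same held for osteoclast markers (6 of 6, median 0.36), lysosome and autophagy genes (21 of 25, median 0.06) and class I antigen presentation genes (13 of 15, median 0.12), with adjusted p = 0.328, 0.747 and 0.704 with an estimated correlation. Mitochondrially encoded genes were lower (1 of 13 above 0, median −0.17; adjusted p = 0.705 with an estimated correlation). Camera's adjusted p ran from 5.40e-05 for the matrix and oxidative phosphorylation genes to 0.0336 for class I. No member was called over all genes, and 3 matrix genes, 3 osteoclast markers and 1 lysosome and autophagy gene were called when adjusted over the list alone. Class I members were Tapbp (0.22 ± 0.083, adjusted p = 0.540) and B2m (0.25 ± 0.13, adjusted p = 0.664). Mitochondrial ones were mt-Co1 (−0.22 ± 0.081, adjusted p = 0.526) and mt-Nd5 (−0.31 ± 0.13, adjusted p = 0.622). Leaving out KO 1 gave 18 called genes and 3 lists, leaving out KO 2 or KO 4 gave 2 genes, and leaving out WT 4 gave 10 lists. Of the 35 ways to divide the 8 libraries into 4 and 4, 20 called as many lists as genotype did.

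At 3 h of LPS, Itgax and Inhba were among the genes higher in KO, and S100a9 and Ly6c2 among those lower. Itgax, the CD11c integrin subunit, lay at 83.6 ± 21.7 CPM in KO and 40.9 ± 4.58 CPM in WT (SD, n = 4; 1.04 ± 0.18 log2, adjusted p = 0.0384). The class I-like gene H2-M2 (0.96 ± 0.12), the protease inhibitor Serpinb9b (0.92 ± 0.15), the monoamine oxidase Maoa (0.88 ± 0.14), Ptgfrn (0.88 ± 0.20) and Inhba, the activin A subunit (0.86 ± 0.13), were also higher, with adjusted p from 0.00526 to 0.0451. Lower in KO were S100a9, a calprotectin subunit of neutrophils and monocytes (−1.08 ± 0.17, adjusted p = 0.00526; 10.0 ± 2.33 against 20.8 ± 2.93 CPM), and Ly6c2, a marker of classical monocytes (−0.93 ± 0.19, adjusted p = 0.0250). Id3 (−0.89 ± 0.16), Cavin1 (−0.87 ± 0.15), Ifitm1 (−0.86 ± 0.14) and the cyclin gene Ccnd2 (−0.77 ± 0.11) were lower too, with adjusted p from 0.00526 to 0.0146. Before LPS, Itgax already lay at 58.5 to 91.8 CPM in KO and 27.2 to 39.995 CPM in WT libraries, though not called. At 12 h, again not called, it lay at 52.1 to 80.4 and 23.2 to 39.6 CPM. S100a9 before LPS lay at 3.59 to 8.31 CPM in KO and 8.59 to 12.2 CPM in WT. For Inhba the 0 h ranges overlapped (0.327 to 1.12 and 0.163 to 0.937 CPM). The Itgax and S100a9 differences are thus not shown to arise with LPS.

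In total edgeR called 76 of 11035 genes at 3 h, 40 higher and 36 lower in KO, 6 of them over 2-fold. Neutrophil markers were lower (0 of 6 above 0, median −0.59, camera adjusted p = 2.74e-07; adjusted p = 0.107 with an estimated correlation). S100a9 and S100a8 (−0.76 ± 0.11, adjusted p = 0.00526) were called over all genes and 4 members adjusted over the list alone. Monocyte markers were lower too (1 of 10 above 0, median −0.44, camera adjusted p = 3.95e-05; adjusted p = 0.0966 with an estimated correlation). Ly6c2 and Vcan (−0.66 ± 0.13, adjusted p = 0.0362) were among the members called, and 3 were called when adjusted over the list alone. The oxidative stress targets of NRF2 (14 of 16 above 0, median 0.14) and the osteoclast markers (7 of 7, median 0.46) were higher by camera (adjusted p = 2.41e-05 and 1.59e-04; adjusted p = 0.229 for both with an estimated correlation). Of their members 0 were called over all genes and 4 and 3 adjusted over the list alone. Oxidative phosphorylation (36 of 38 above 0, median 0.12) and lysosomal genes (18 of 24, median 0.04) were higher and NF-κB pathway genes lower (5 of 23 above 0, median −0.10). Their camera adjusted p = 8.19e-06, 0.0151 and 0.00382 became adjusted p = 0.519, 0.519 and 0.308 with an estimated correlation, with 0, 0 and 1 members called when adjusted over the list alone and 0 over all genes. The NF-κB feedback gene Nfkbid differed by −0.67 ± 0.16 (adjusted p = 0.0564).

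The number of genes called at 3 h was 160 without KO 1, 39 without KO 3, 37 without KO 4, 18 without WT 2 and 32 without WT 3. In place of 7 lists, 13, 11 and 14 were called without KO 3, WT 1 and WT 4. H2-M2, Serpinb9b, Maoa, Inhba, S100a9, S100a8, Ifitm1 and Ccnd2 were called in all 8 such fits. Calls were lost for Cavin1 without WT 2 (adjusted p = 0.0593), Id3 without KO 4, WT 2 or WT 3 (highest adjusted p = 0.0931), and Ly6c2 without KO 3, WT 1 or WT 2 (0.138). They were also lost for Itgax without KO 3 or any 1 WT library (0.136), Vcan without KO 2, KO 3, KO 4, WT 2 or WT 3 (0.150) and Ptgfrn without any 1 library (0.145). One fit of all 40 libraries ended the calls of H2-M2, Ptgfrn, Inhba, Ly6c2, Id3, Cavin1 and Vcan, and limma with the animal as a random effect those of H2-M2, Ptgfrn, Ly6c2 and Vcan. Without the 2 male animals those of Itgax, Ptgfrn, Ly6c2 and Vcan were lost.

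At 6 h the gene that differed most clearly was Inhba, at 70.9 ± 4.31 CPM in KO and 26.9 ± 2.64 CPM in WT (SD, n = 4; 1.38 ± 0.11 log2, edgeR adjusted p = 3.83e-06). Interferon-inducible genes were higher in KO. The immunity-related GTPase Iigp1 lay at 2704 ± 109 against 1622 ± 169 CPM (0.72 ± 0.075, adjusted p = 1.78e-04). The GTPase Tgtp1 (0.45 ± 0.076), the guanylate-binding protein Gbp4 (0.39 ± 0.073) and the cytokine signalling inhibitor Socs1 (0.50 ± 0.089) were higher too, as were Ifit1bl1 (0.51 ± 0.071), Oasl1 (0.52 ± 0.094), the RNA sensor Ifih1 (0.37 ± 0.074) and Cmpk2 (0.34 ± 0.069). Adjusted p of these 7 ran from 0.00228 to 0.0217. Higher as well were the NRF2 targets Prdx1 (0.45 ± 0.066, adjusted p = 0.00273), Srxn1 (0.62 ± 0.097, adjusted p = 0.00425) and Gclm (0.67 ± 0.11, adjusted p = 0.00752). The protease genes Mmp9 (1.17 ± 0.16, adjusted p = 0.00228), Ctsk (0.96 ± 0.19, adjusted p = 0.0181), Mmp12 (0.60 ± 0.11, adjusted p = 0.0144) and Ctsl (0.35 ± 0.076, adjusted p = 0.0340) were higher. So were the growth factor Hbegf (1.12 ± 0.20, adjusted p = 0.0217), Serpinb9b (1.03 ± 0.16), Itgax (0.94 ± 0.17), the cytokine Tnfsf15 (0.73 ± 0.13) and the stress factor Atf3 (0.41 ± 0.081), the last 4 with adjusted p from 0.00412 to 0.0260.

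Genes lower in KO at 6 h were Wfdc21 (−1.23 ± 0.28, adjusted p = 0.0433), a neutrophil marker, and Herpud1, an endoplasmic reticulum stress gene (−0.78 ± 0.12, adjusted p = 0.00451). Also lower were Id3 (−0.97 ± 0.21), Fgd2 (−0.82 ± 0.19), Ifitm1 (−0.74 ± 0.12), Klf7 (−0.71 ± 0.11), the costimulatory ligand Icosl (−0.70 ± 0.13) and Klf2 (−0.58 ± 0.13). In total edgeR called 106 of 10518 genes, 88 higher and 18 lower in KO, 6 of them over 2-fold.

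By list, 17 of 18 interferon gamma-inducible GTPases and targets lay above 0 at 6 h (median 0.24), 6 called over all genes and 12 adjusted over the list alone. Camera's adjusted p = 8.10e-18 held (adjusted p = 0.0297 with an estimated correlation). Of 41 type 1 interferon response genes 39 lay above 0 (median 0.14), 5 called over all genes and 5 adjusted over the list alone (camera adjusted p = 1.97e-11; adjusted p = 0.0376 with an estimated correlation). Osteoclast markers (7 of 7 above 0, median 0.25; 2 called, 3 adjusted over the list alone) and TGF-β and matrix genes (14 of 17 above 0, median 0.07; 2 called, 4 adjusted over the list alone) were higher. Neutrophil markers were lower (1 of 7 above 0, median −0.54; 1 called, 4 adjusted over the list alone). Their camera adjusted p = 1.76e-06, 6.81e-05 and 9.31e-05 held with an estimated correlation (adjusted p = 0.0297, 0.0346 and 0.0361 with an estimated correlation). Mmp9 stands in both the matrix and the osteoclast list. All 7 osteoclast markers, 5 of 7 neutrophil markers and 9 of 10 monocyte markers lay at a mean of 5 CPM or more in these cultures, and 2 of each list stand in another list. Monocyte markers at 6 h had a median of −0.14 (adjusted p = 0.445) and macrophage identity genes of 0.07 (adjusted p = 0.0662).

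A further 10 lists were called at 6 h and lost with an estimated correlation. NRF2 targets were higher (15 of 16 above 0, median 0.24; 3 called, 7 adjusted over the list alone; camera adjusted p = 8.39e-13; adjusted p = 0.0698 with an estimated correlation). Chemokines (15 of 17 above 0, median 0.21), macrophage activation and metabolism genes (15 of 19, median 0.16), inflammatory cytokines (12 of 17, median 0.24) and glycolysis genes (14 of 17, median 0.13) were higher. They had adjusted p = 0.231, 0.0844, 0.0786 and 0.231 with an estimated correlation. Higher too were oxidative phosphorylation (32 of 38, median 0.10), lysosome (20 of 25, median 0.06), LPS restraint (12 of 21, median 0.25) and immediate early genes (11 of 16, median 0.11). They had adjusted p = 0.424, 0.231, 0.0887 and 0.105 with an estimated correlation. Cholesterol synthesis genes were lower (3 of 22 above 0, median −0.15; adjusted p = 0.322 with an estimated correlation). Camera's adjusted p for these 9 lists ran from 1.94e-05 to 0.00204. In the order given, 0, 0, 1, 0, 0, 1, 3, 1 and 0 of their members were called over all genes, and 0, 6, 4, 1, 0, 4, 10, 7 and 0 adjusted over the list alone. The last counts were, in LPS restraint, 8 higher and 2 lower and in immediate early genes 6 higher and 1 lower. The called LPS restraint genes were Socs1, Atf3 and Klf2, the last of these lower in KO. Not called were the linear ubiquitin machinery (median 0.05, adjusted p = 0.510), TLR4 signalling (−0.02, adjusted p = 0.749), inflammasome and pyroptosis (−0.08, adjusted p = 0.770) and apoptosis and necroptosis genes (median 0.01 and mean −0.01, adjusted p = 0.770). Of the 35 divisions of the 8 libraries, 3 called at least 15 lists, the genotypes' own included.

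The number of genes called at 6 h was 37 without KO 1, 60 without KO 2, 57 without KO 3 and 42 without WT 2. Inhba, Mmp9, Serpinb9b, Iigp1, Tgtp1, Ifit1bl1, Oasl1, Prdx1, Srxn1, Gclm, Herpud1, Ifitm1 and Klf7 were called in all 8 fits with 1 library left out. The call was lost for Socs1 without WT 2 (adjusted p = 0.0505), Gbp4 without KO 1 (0.0594) and Atf3 without KO 1, KO 2 or WT 2 (highest adjusted p = 0.0825). It was lost for Mmp12 without KO 3, KO 4, WT 2 or WT 3 (0.0658), Cmpk2 without KO 2, KO 3, KO 4 or WT 2 (0.0723) and Ifih1 without KO 1, KO 3, WT 2 or WT 3 (0.107). The same held for Icosl without KO 1, KO 4, WT 2 or WT 3 (0.0888) and Ctsk without KO 1, KO 2, WT 2 or WT 3 (0.108). It was also lost for Itgax without WT 2 or any 1 KO library (0.0808), and for Id3 and Tnfsf15 without WT 2, WT 3 or any 1 KO library (0.153 and 0.0889). The remaining losses were Hbegf without any 1 library but KO 2 and WT 1 (0.0888), Ctsl without any 1 but KO 4 and WT 1 (0.135), Klf2 without any 1 but WT 1 (0.118), and Fgd2 and Wfdc21 without any 1 but WT 3 (0.196 and 0.153). One fit of all 40 libraries ended the calls of Mmp9, Id3, Fgd2, Icosl, Ifit1bl1, Ifih1, Cmpk2, Tgtp1, Socs1, Gbp4, Ctsl and Wfdc21. Limma with the animal as a random effect ended those of Id3, Fgd2, Cmpk2, Socs1, Gbp4, Klf2, Ctsl and Wfdc21. Without the 2 male animals those of Hbegf, Itgax, Id3, Fgd2, Ifih1, Cmpk2, Klf2, Ctsl and Wfdc21 were lost.

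**Figure D2:**
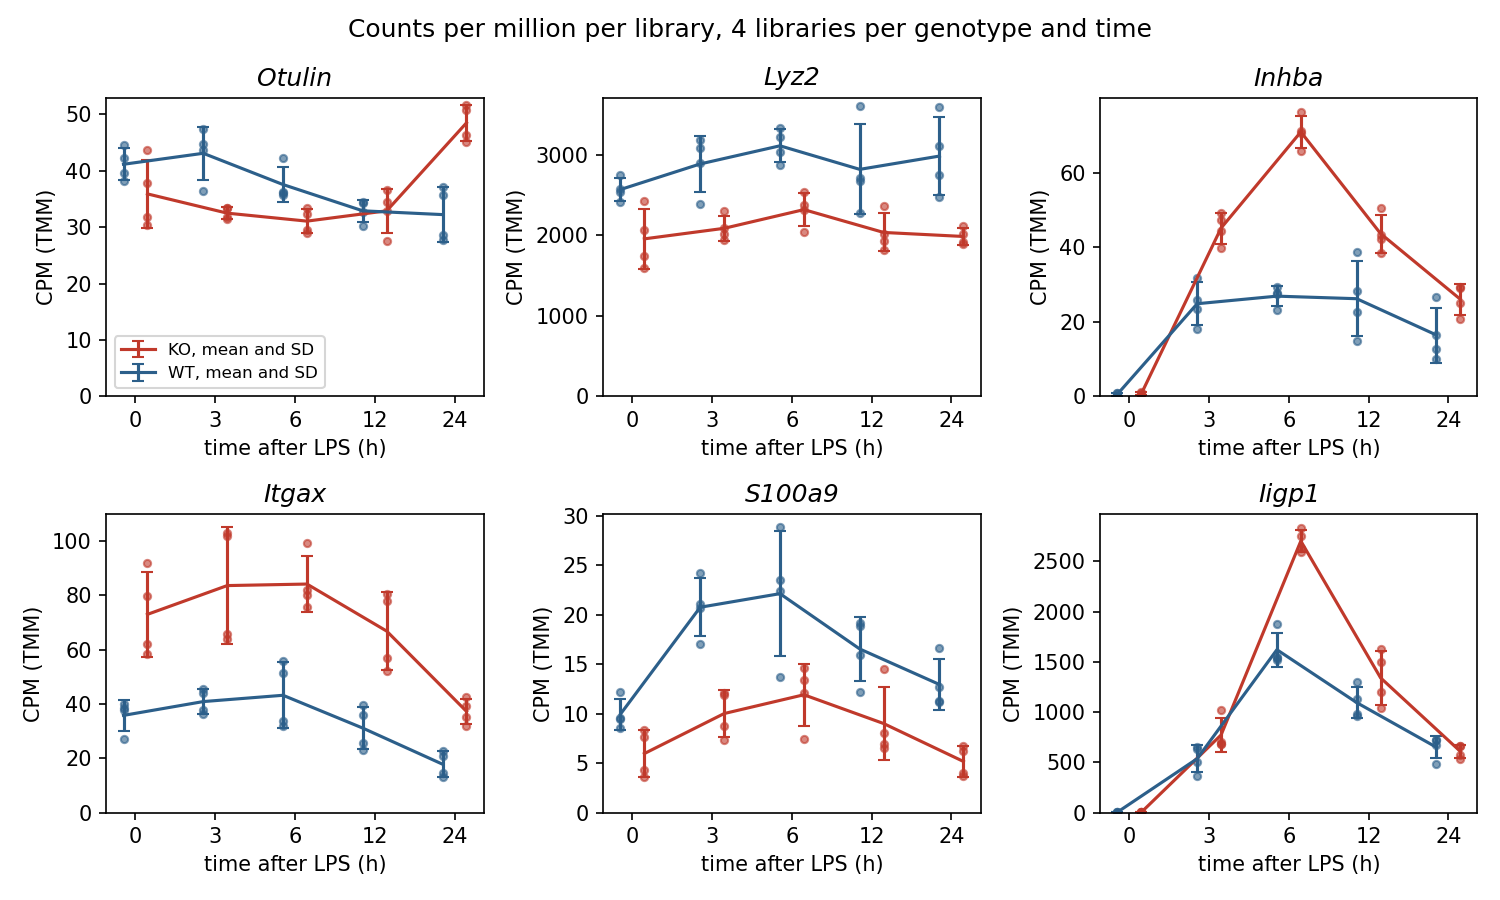
CPM of Otulin, Lyz2, Inhba, Itgax, S100a9 and Iigp1 against hours of LPS, 1 point per library, with the mean and SD of the 4 libraries of each genotype. At 6 h Inhba has a mean of 70.9 CPM in KO and 26.9 CPM in WT, and Iigp1 of 2704 and 1622 CPM.

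At 12 h, 5 of 10783 genes were called by edgeR. Higher in KO were the protease inhibitor gene Serpinb1a (1.20 ± 0.16 log2, SE, n = 4; adjusted p = 0.0291) and Procr, the endothelial protein C receptor, at 487 ± 34.3 against 222 ± 57.0 CPM (1.11 ± 0.15, adjusted p = 0.0291). So were the glycolytic regulator Pfkfb3 (0.81 ± 0.12, adjusted p = 0.0426) and Crbn, which encodes the ubiquitin ligase substrate receptor cereblon (0.76 ± 0.12, adjusted p = 0.0426). Fgd2 was lower (−1.21 ± 0.18, adjusted p = 0.0426). All 16 NRF2 targets lay above 0 (median 0.27; 3 adjusted over the list alone), as did all 17 glycolysis genes (median 0.18; 1 called, 5 adjusted over the list alone). Their camera adjusted p = 6.12e-11 and 1.71e-10 became adjusted p = 0.304 and 0.128 with an estimated correlation. Of 22 cholesterol synthesis genes 2 lay above 0 (median −0.24; camera adjusted p = 7.89e-07; adjusted p = 0.330 with an estimated correlation). Oxidative phosphorylation (37 of 38 above 0, median 0.15), heat shock (10 of 11, median 0.20), macrophage activation and metabolism (15 of 19, median 0.15), TGF-β and matrix (14 of 18, median 0.17) and lysosomal genes (21 of 25, median 0.08) were higher by camera. In that order they had adjusted p = 0.516, 0.196, 0.330, 0.196 and 0.349 with an estimated correlation. Cell cycle genes were lower (9 of 31 above 0, median −0.18; adjusted p = 0.676 with an estimated correlation). Camera's adjusted p ran from 7.69e-06 to 0.0110 for these 6 lists. Of their members 0, 2, 2, 2, 1 and 0 were called when adjusted over the list alone, and 0 over all genes. Among other-cell lists, osteoclast markers were higher (6 of 7 above 0, median 0.44, adjusted p = 8.50e-04; adjusted p = 0.202 with an estimated correlation), with 3 members higher and 1 lower when adjusted over the list alone. Neutrophil markers were lower (2 of 6 above 0, median −0.18, adjusted p = 0.0412; adjusted p = 0.330 with an estimated correlation), with 2 members called when adjusted over the list alone. The heat shock gene Hspa1a differed by 0.80 ± 0.14 (adjusted p = 0.0986) and Nos2, the inducible nitric oxide synthase, by 0.79 ± 0.18 (adjusted p = 0.199). Without KO 1, WT 2, WT 3 or WT 4 no gene was called. Without KO 2 only 1 was, and without KO 3, KO 4 and WT 1 the counts were 12, 18 and 10. A division of the 8 libraries that put those of both male animals on one side called 25 genes. Without the 2 male animals the calls of all 5 genes were lost.

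At 24 h, 9 of 11122 genes were called by edgeR, 6 higher and 3 lower in KO. Itgax (1.08 ± 0.16 log2, SE, n = 4), the adhesion molecule Cadm1 (0.64 ± 0.10), Tspan13 (0.60 ± 0.098), Bst1 (0.47 ± 0.080) and Il1rn (0.46 ± 0.076) were higher, each with an adjusted p = 0.0387. Il1rn, the interleukin 1 receptor antagonist, lay at 1542 ± 41.5 against 1115 ± 100.1 CPM (SD). S100a9 (−1.31 ± 0.22) and Lyz2 were lower at the same adjusted p. Maoa, at 29.4 ± 3.41 against 14.5 ± 2.55 CPM (SD), was 2.01-fold higher (adjusted p = 0.0382). All 22 cholesterol synthesis genes lay below 0 (median −0.22; 0 called, 2 adjusted over the list alone; camera adjusted p = 1.27e-07; adjusted p = 0.626 with an estimated correlation). One of them was Hmgcs1 (−0.47 ± 0.088, adjusted p = 0.0704). TGF-β and matrix (14 of 18 above 0, median 0.24), glycolysis (15 of 17, median 0.11), oxidative phosphorylation (34 of 38, median 0.10) and NRF2 genes (14 of 16, median 0.12) were higher by camera. They had adjusted p = 0.146, 0.626, 0.776 and 0.776 with an estimated correlation. Higher by camera too were lysosomal (20 of 25, median 0.04), heat shock (10 of 11, median 0.12), macrophage activation (13 of 19, median 0.06) and cell cycle genes (26 of 32, median 0.11). They had adjusted p = 0.646, 0.646, 0.776 and 0.776 with an estimated correlation. Camera's adjusted p of these 8 lists ran from 1.02e-05 to 0.0226. Of their members 3, 1, 0, 0, 0, 1, 2 and 0 were called when adjusted over the list alone, and 0 over all genes. The type 1 interferon response (11 of 42 above 0, median −0.07) and the interferon gamma-inducible genes (2 of 18, median −0.11) were lower by camera (adjusted p = 2.27e-04 and 0.0143; adjusted p = 0.776 for both with an estimated correlation), with 3 and 0 members called when adjusted over the list alone. Mx2 lay at −0.44 ± 0.11 (adjusted p = 0.185). Osteoclast markers were higher (5 of 6 above 0, median 0.41, adjusted p = 0.00127; adjusted p = 0.146 with an estimated correlation), with 2 members called when adjusted over the list alone. Neutrophil markers were lower (2 of 6 above 0, median −0.15, adjusted p = 0.0226; adjusted p = 0.626 with an estimated correlation), with 2 called in that way. The count of genes was 0 without KO 1, KO 2, WT 2 or WT 4, 1 without WT 3, 3 without KO 3 and 20 without KO 4. Without WT 3, 8 lists were called. One fit of all 40 libraries ended the calls of Bst1 and Il1rn, and limma with the animal as a random effect that of Il1rn. Of the genes named here Maoa alone was called without the 2 male animals.

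Inflammatory cytokine and cell death genes fixed for every comparison did not pass the test between genotypes at any time. Tnf lay at 785 ± 33.6 CPM in KO and 734 ± 78.8 CPM in WT at 3 h (SD, n = 4; edgeR adjusted p = 0.707) and at 643 ± 43.1 and 596 ± 112 CPM at 6 h (adjusted p = 0.819). Il1b lay at 1326 ± 226 and 1345 ± 212 CPM at 3 h (adjusted p = 0.979), and Il6 at 343 ± 57.5 and 266 ± 118 CPM at 6 h (adjusted p = 0.791). For Il1b the 95% interval of the difference at 3 h ran from −0.30 to 0.26 log2, for Tnf from −0.07 to 0.27, and for Il6 at 6 h from −0.55 to 1.24. Nlrp3 (182 and 178 CPM at 3 h, adjusted p = 0.926), Ripk3 (adjusted p = 0.566 at 0 h, the lowest of its 5) and Mlkl (83.9 and 79.3 CPM at 6 h, adjusted p = 0.828) were likewise not called.

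Calls at some pairs of times overlapped. Of the genes higher in KO, 19 were called at both 3 h (39) and 6 h (88 of 10332 genes tested at both), where independent lists would share 0.332. Of the lower genes 6 were called at both (36 and 18; 0.0627 for independent lists). At 3 h and 24 h, 3 higher and 2 lower calls were shared (0.0224 and 0.00977 for independent lists), and at 6 h and 12 h 3 higher and 1 lower. At 6 h and 24 h, 3 higher and 1 lower calls were shared too. At 3 h and 12 h 0 calls were shared, and at 12 h and 24 h 0 as well. If libraries of one number come from one animal, as was assumed, animal-specific differences can add to these overlaps. Of the genes called at 6 h, 74 of 90 had the same direction at 0 h, 101 of 106 at 3 h, 104 of 105 at 12 h and 78 of 105 at 24 h.

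Whether LPS acted differently on the 2 genotypes was tested directly. By edgeR, 0 of 12165, 0 of 12096 and 0 of 12164 genes had a different response in KO at 3, 6 and 12 h. At an unadjusted p under 0.05 there were 342, 529 and 396 genes, and DESeq2 called 2, 11 and 1. At 24 h 1 of 12226 genes was called, a pseudogene with a mean of 1.77 CPM, and 0 with the animal as a block. That more genes were called between genotypes at 3 and 6 h than at 0 h is therefore not shown to be a change in the LPS response. Leaving out 1 animal gave 4 genes at 6 h without WT 1 and 1 gene at 12 h without KO 4. At 24 h the count was 1 without KO 1 and 0 without any of the other 7 animals.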

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

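No test in this part was chosen after its result was seen; the pseudogene in the last paragraph falls outside the naming rule and was named after its values were seen. In each group of 4 libraries, the gap between the most distant library and the nearest of the others was set against the whole range of the group, for library properties and for the genes named in the comparisons. Of 412 such groups 26 had a gap above Dixon's 95% critical value, where chance gives about 1 in 20, or 20.6. No explanation was tested for them.

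Library totals stood apart in KO 2 at 12 h (5264452 counts against 4290997 to 4455350 in the others; gap 0.831 of the range), WT 3 at 12 h (6195781 against 4007478 to 4123314; 0.947) and WT 3 at 24 h (6166312 against 4209612 to 4430400; 0.887). The share of counts in ribosomal protein genes stood apart in KO 4 at 12 h (3.33% against 2.53% to 2.65%; 0.853) and in WT 2 at 24 h (2.13% against 2.33% to 2.36%; 0.853).

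Among genes fixed for every comparison, Otulin stood apart in WT 2 at 6 h (42.3 CPM against 35.7 to 36.2; gap 0.927 of the range), Tnf in KO 1 at 6 h (579 against 661 to 669 CPM; 0.908), Il1b in WT 2 at 6 h (1225 against 1090 to 1092 CPM; 0.985) and Il1b in KO 4 at 12 h (716 against 453 to 485 CPM; 0.877). Il6 in KO at 0 h was counted in KO 2 alone, at 0.372 CPM (gap 1 of the range).

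Among genes named for a difference between KO and WT at 3 or 6 h, H2-M2 stood apart in WT 1 at 3 h (85.8 against 71.8 to 72.3 CPM; gap 0.970 of the range), and at 6 h Mmp9 in WT 4 (11.7 against 8.41 to 8.77 CPM; 0.889), Hbegf in WT 1 (33.8 against 16.8 to 19.5 CPM; 0.841), Serpinb9b in WT 1 (30.0 against 21.1 to 22.6 CPM; 0.832), Iigp1 in WT 3 (1875 against 1517 to 1554 CPM; 0.896) and Gbp4 in KO 4 (317 against 301 to 303 CPM; 0.837). At 12 h these were Serpinb1a in KO 2 (18.4 against 24.6 to 25.0 CPM; 0.939), Procr in KO 4 (537 against 466 to 477 CPM; 0.845), Procr in WT 1 (307 against 183 to 201 CPM; 0.856) and Crbn in KO 1 (130.3 against 105 to 109 CPM; 0.876). The single high WT 1 library for Procr lay below all KO libraries at 12 h.

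Atp5g1, an ATP synthase gene, stood apart in KO 1 at 0 h (78.0 against 60.4 to 63.3 CPM; gap 0.831 of the range). At 24 h in WT the gaps were Socs1 in WT 1 (32.8 against 38.8 to 39.4 CPM; 0.911), Mmp12 in WT 1 (640 against 397 to 417 CPM; 0.917), Cfb in WT 4 (515 against 591 to 597 CPM; 0.922) and Cdc20 in WT 2 (0.892 against 0.461 to 0.475 CPM; 0.966). Slfn1 in WT at 0 h was counted in WT 4 alone, at 0.156 CPM (gap 1 of the range).

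The pseudogene Gmfg-ps was the only gene whose LPS response differed between genotypes by edgeR, at 24 h (interaction 4.77 ± 0.77 log2, SE, adjusted p = 0.0399; 16 libraries). It lay at a mean of 1.77 CPM, and no gene was called with the animal as a block. Tags of a pseudogene and its parent, here Gmfg, can be exchanged, so the value is uncertain.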

How the results depend on the processing

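Sex as a covariate and leaving out the male animals were chosen after seeing the data; all other alternatives were set beforehand. The LPS counts stayed within 1.5 times under all 6 alternatives and with each library left out (WT 6211 to 6446, 7969 to 8193, 7997 to 8219 and 8133 to 8310 at 3, 6, 12 and 24 h; KO 5375 to 5670, 7469 to 7709, 7437 to 7940 and 7513 to 7910). The genotype counts did not. In the order 0, 3, 6, 12 and 24 h, where edgeR called 0, 76, 106, 5 and 9 genes, leaving out 1 library gave 0 to 18, 18 to 160, 37 to 148, 0 to 18 and 0 to 20. Without the filter on low counts 177, 359, 344, 158 and 163 genes were called, and with DESeq2 27, 147, 183, 57 and 56. One fit of all 40 libraries gave 9, 35, 125 and 32 at 0, 3, 12 and 24 h. Limma with the animal as a random effect gave 19, 133 and 40 at 0, 12 and 24 h (consensus correlation 0.120). Sex as a covariate gave 1 at 0 h and 20 at 12 h, and leaving out the 2 male animals 2 at 12 h and 1 at 24 h. At 6 h these last 4 settings stayed within 1.5 times of 106. For the fits with fewer libraries, fewer calls follow in part from fewer samples; otherwise the cause was not tested.

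KO and WT animals of one number were not paired: their deviations at the same time correlated with a mean r across genes of −0.0655 (over 0.1 in 1 of 20 pairs), and not every library correlated best with its own number. The replicate block gave 5, 26, 0 and 0 genes at 0, 3, 12 and 24 h and 82 at 6 h. Within a genotype the number was taken to mark the animal; there the block ended the 1 interaction call at 24 h (0 genes), called 0 genes at 3, 6 and 12 h as without it, and kept the LPS counts within 1.5 times.

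Of the lists called by camera (6, 7, 15, 11 and 13), 0, 0, 5, 0 and 0 were called with an estimated correlation, and fry called 0, 3, 1 and 0 at 0, 3, 12 and 24 h and 10 at 6 h. At 3 h 13 lists were called without the filter and 13 without the male animals, and at 0 h 11 in one fit of all 40 libraries; leaving out 1 library gave 3 to 10, 7 to 14, 15 to 17, 8 to 15 and 8 to 13. For the interaction (0, 0, 0 and 1 genes by edgeR at 3, 6, 12 and 24 h), no filter gave 4, 11, 40 and 5, DESeq2 gave 2, 11 and 1 at the first 3 times, leaving out the male animals gave 1 at 3 h and 1 at 6 h, and leaving out 1 animal gave 0 to 0, 0 to 4, 0 to 1 and 0 to 1; 342, 529, 396 and 474 genes had an unadjusted p under 0.05.

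Over the 281 values of named genes, 4231 alternative values were computed. Of these 3816 kept their side of the threshold, 287 lost the call and 128 gained one. Of the called values 0 changed sign, while 91 uncalled ones, counted among the 3816, did. Leaving out single libraries accounted for 193 of the lost calls, the 2 male animals for 27, the replicate block for 26 and the fit of all 40 libraries for 23. DESeq2's size factors in edgeR changed 1 of 281. Depth limits low genes: in simulated counts at 6 h, 12 of 53 changes of 1.5-fold were recovered below the median level of 26.1 CPM and 41 of 47 above it.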

Other observations

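Summing the 5 libraries of each number within a genotype, taken as 1 animal, and testing those sums, were chosen after seeing the data, as were the tests of fewer neutrophils and of library scaling, the test of fewer mature macrophages and the value without male animals; the genes named here from the sums, and Mmp8, Lcn2, Csf3r and Ngp, were chosen after their values were seen.

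Over the summed counts, 69 of 14241 genes differed between the 4 KO and 4 WT animals by edgeR, 55 higher and 14 lower in KO. Procr, the receptor of protein C, was the most clearly higher (0.86 ± 0.079 log2, SE, adjusted p = 6.48e-04), followed by Maoa (0.83 ± 0.090, adjusted p = 0.00222) and the cereblon gene Crbn (0.57 ± 0.069, adjusted p = 0.00432). Also higher were the protease genes Mmp9, at 1.25 ± 0.22 (adjusted p = 0.0482), Ctsk, at 0.72 ± 0.12 (adjusted p = 0.0212) and Mmp12, at 0.58 ± 0.092 (adjusted p = 0.0188). So were Prdx1 (0.35 ± 0.055, adjusted p = 0.0145), Prdx6 (0.36 ± 0.060, adjusted p = 0.0181) and Srxn1 (0.34 ± 0.059, adjusted p = 0.0271), and Itgax (1.02 ± 0.17, adjusted p = 0.0443) and Inhba (0.96 ± 0.12, adjusted p = 0.00746). The ubiquitin gene Ubb (0.28 ± 0.054, adjusted p = 0.0408), the ubiquitin ligase gene Trim25 (0.28 ± 0.054, adjusted p = 0.0414), the fatty acid binding protein gene Fabp4 (0.51 ± 0.097, adjusted p = 0.0463) and the β-glucan receptor gene Clec7a (0.39 ± 0.078, adjusted p = 0.0463) were higher too. For all 69 called genes the values of the 4 KO and the 4 WT animals did not overlap. Lower were S100a9 (−0.995 ± 0.16, adjusted p = 0.0181), S100a8 (−0.45 ± 0.085, adjusted p = 0.0394), Lyz2 (−0.47 ± 0.064, adjusted p = 0.00746), Ccnd2 (−0.51 ± 0.089, adjusted p = 0.0316) and Ifitm1 (−0.55 ± 0.067, adjusted p = 0.00432). With sex as a covariate 108 genes were called, all 69 among them; without the male animals 45 of 14311 were called, 31 of them among the 69. Of the 35 divisions of the 8 animals 1, the real one, called at least 69 genes, and the highest other called 1.

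The first pattern is the lower level of neutrophil markers in KO at 3 and 6 h, with a median of −0.54 over 7 markers at 6 h; the call at 6 h held with an estimated correlation (adjusted p = 0.0361) and that at 3 h did not (adjusted p = 0.107 with an estimated correlation). Without the male animals, KO 3 and WT 4, the median was −0.43 (SE over members 0.21), so the lower level did not rest on them alone. Sex was balanced between the genotypes and the SE over members does not measure the spread between animals, so this weighs little. The test of library scaling decided nothing, because DESeq2's size factors move all genes alike. They left the list −0.54 from the median of all genes. Fewer neutrophils or their precursors in the KO cultures may account for it, and cannot be told apart from lower expression in the same cells. The members spread 2.38 times as widely as their mean standard error, over the bound of 2 set against a uniform loss, but that bound was set aside after the value was seen, because 83.7% of the list's CPM comes from genes other than S100a8 and S100a9, above all Mmp8 (157 CPM, 0.00 log2), whose level in macrophages would hide a small share of neutrophils. Lcn2 (−0.18) and Csf3r (−0.10) moved little, and Wfdc21 (−1.23), Ngp (−1.24), S100a9 (−0.91) and S100a8 (−0.54) more; 5 of the 7 lay at a mean of 5 CPM or more and 2 stand in another list.

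The next pattern is the higher interferon response in KO at 6 h. If KO cells stood at another point of the LPS time course, the KO minus WT difference was predicted to follow the WT change from 3 h to 12 h. Pearson's r across 10509 genes was −0.0360 (Spearman's rho −0.0579), so the difference did not follow that net change. Genes that peak or dip between 3 h and 12 h can show little net change, so a shift of the time course is not decided. For the list itself this measure decides nothing, since its WT median above 0 h was 4.39, 5.35 and 4.85 at 3, 6 and 12 h (5.18 and 4.84 at 6 and 12 h with 1 member at its floor), highest at 6 h, so a shift of the interferon response alone stays open. Without the male animals the list's median was 0.14 (SE over members 0.026, 41 members), so it did not rest on them alone. The limits given for the neutrophil markers hold here too. Of the 35 divisions of the 8 libraries 1, the real one, had a median as far from 0, at 0.14. The highest other reached 0.089. A higher interferon response of KO macrophages at 6 h thus remains a hypothesis, found and tested on the same data, while at 24 h the list had a median of −0.07. For this pattern and the neutrophil markers, loss of Otulin cannot be told apart from the Cre that all KO and no WT animals carry.

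The last pattern is the lower Lyz2 in KO, called at 3, 6 and 24 h. The macrophage identity list did not fall with it, with a median of 0.0734 at 6 h (SE over its 23 members 0.052). That SE does not measure the spread between animals. In macrophage cultures TMM scaling can also take up a loss shared by most genes. Fewer mature macrophages are therefore not decided as a source of the lower Lyz2. Genes carried along with the Cre insertion from another strain could add to it: of 40 measured neighbours of Lyz2 in the RefSeq gene order (GRCm38.p6), 9 had an unadjusted p under 0.05 at 6 h, equal to the 95th percentile of 1000 random windows (9; median 4), so this cannot be told apart from chance. The insertion of Cre into Lyz2 itself, which the design names, stays open as untested.

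Other divisions of the samples bear on the counts. For KO against WT, 1 of 35 divisions, the real one, called at least as many genes at 3, 6 and 24 h. Genotype called 76, 106 and 9 genes there, and the highest other division 50, 1 and 1. The share was under 0.05 at these times, but 1 of 35 is the smallest share possible and the 5 times were not adjusted for. The 24 h count also fell to 0 without KO 1. At 12 h 2 of 35 divisions called at least the 5 genes called by genotype, so chance cannot be excluded. The highest other called 25, with the libraries of both male animals on one side. Many other divisions put them on one side too, so this does not single out sex. With sex as a covariate 20 genes were called. At 0 h all 35 called at least 0 genes (highest other 1). For lists chance cannot be excluded at any time: 20 of 35 divisions at 0 h (6 lists by genotype; highest other 12), 22 at 3 h (7; 16), 3 at 6 h (15; 15), 9 at 12 h (11; 17) and 3 at 24 h (13; 15) called as many. For the response to LPS, 1 of 35 divisions, the real one, called as many genes at each time. In WT these were 6640, 8277, 8282 and 8489, with highest others of 1, 0, 0 and 1. In KO they were 5853, 7791, 7797 and 7917, with highest others of 1, 0, 494 and 0. The share was under 0.05 each time, again the smallest possible. The 494 came from a division with both libraries of the male KO animal on one side; of the 7 other divisions that part all 4 animals, the highest called 0 at that time. For the interaction, all 35 divisions called at least 0 genes at 3, 6 and 12 h (highest others 3, 1 and 4), and 1 called at least 1 at 24 h (highest other 0).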
